A study of Homo sapiens with 6 samples.

How the data were processed

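Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in H1299 cells, an established human non-small cell lung cancer line, with an antibody against YAP or an antibody against TAZ. YAP and TAZ are related transcriptional coactivators of the Hippo pathway that reach DNA through partner proteins such as the TEAD factors. Per the labels' protocols, the cells had been serum starved for 18 hours before nuclei were isolated and sonicated. The series held 6 samples: 2 YAP libraries, 2 TAZ libraries and 2 input libraries. A peak list was used for each of the 4 antibody libraries, and the input libraries entered only through the lists called against them. The replicate numbers came from the labels. Nothing in the labels said that replicates came from separate cultures, so every spread given here is the spread between libraries, which may be technical.

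Per the submitters' processing notes, cutadapt, Bowtie2, SAMtools and MACS2 were used with the human genome build hg19; versions and settings were not given in the sources used here. The deposited lists were broad peaks called separately in each library against an input. The peak names inside all 4 deposited lists named one common input, whereas the names of the lists pointed to a different input for each replicate number. Which input each library was compared with is therefore unsettled, and part of any overlap between lists may come from input reads that they share. The fold in the deposited lists is the authors' ratio of ChIP signal to input across a peak. The deposited −log10 p and −log10 q values are those of the peak caller. The deposited score was 10 times the −log10 q, cut to a whole number, in at least 99.99% of the peaks of each library, and it was not used further. The smallest deposited −log10 q lay between 1.00 and 1.02 in the 4 lists, which corresponds to a q-value of about 0.1; the authors' threshold itself was not given in the sources used here. Fold, −log10 p and −log10 q were used to describe, rank and filter peaks within a list.

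A peak list holds no read totals, so the sequencing depth of each library is unknown. A deeper library gives more peaks and larger −log10 q values at the same fold, so the number of deposited peaks was not read as an amount of binding. To keep list length from setting the overlaps, each library was represented by its strong peaks. These were the 20000 peaks on chromosomes 1 to 22 and X with the highest −log10 q, with ties ordered by −log10 p, fold and position. Regions were the strong peaks of all 4 libraries merged where they overlapped by at least 1 bp. A region was reproducible for an antibody if strong peaks of both its libraries overlapped it, and shared if it was reproducible for both antibodies. A reproducible YAP region was called YAP-selective if no deposited peak of either TAZ library, of any rank, overlapped it; TAZ-selective regions were defined likewise. Coordinates are hg19 and count from 1.

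The overlap of a pair of libraries was given as the Jaccard index, the bases covered by strong peaks of both libraries divided by the bases covered by either. Chance levels came from 100 random circular shifts of one list along each chromosome, or of both TAZ lists together for the region classes. A further set of 100 shifts by 20 to 100 kb kept the local density of peaks. Shares have 95% Wilson intervals, which cover counting error over peaks or regions only and not the variation between libraries. Agreement of the authors' fold was given as Spearman's rho across regions with strong peaks in both libraries. With 2 libraries per antibody, an exact two-sided permutation test cannot give a p below 0.333, and the 4 libraries can be split into pairs in 3 ways: by antibody, by replicate number and crossed. The similarity contrasts were therefore set beside the same contrast in the other splits. Relations across the 23 chromosomes used permutation tests with 100000 resamples and Benjamini-Hochberg adjustment over the 14 relations computed. The gene number per chromosome was the number of protein-coding genes in the RefSeq table, which follows another build (GRCh38.p14); only its counts were used, never its coordinates, and they were divided by the hg19 span up to the last peak end.

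The definitions of strong peaks, regions and region classes were fixed before the data were examined. So were the tests of peak number, similarity, region classes and rank agreement, and most alternative settings. These alternatives were ranking by fold, 5000 or 50000 strong peaks per library, all deposited peaks, a reciprocal overlap of 50%, a q-value of at most 0.01, a fold of at least 4, all sequences in the lists, the replicate number as a block, and each library left out in turn for the similarity and the region classes. Lists shortened to the length of the shortest, the removal of peaks near long peak-free stretches, the local shifts, the other splits of the region classes, the restriction to pairs of different numbers, and the alternatives for the rank agreement were chosen after seeing the data, as was leaving out libraries for the number of peaks. Several results were not part of that plan. They are the relations across chromosomes, the counts in windows, the widths of region classes, their distance from peak-free stretches, and the strong peaks without overlap elsewhere. A long peak-free stretch was one of at least 1 Mb without a deposited peak in any library, and a peak or region was near one if it lay within 1 Mb of it.

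The rule for regions named by position was also fixed beforehand: the 5 regions of each class with the lowest sum of ranks over the libraries that define the class. An hg19 gene annotation and an hg19 sequence were not used here. The planned analyses of genomic features, sequence motifs, genes with a peak at the promoter and gene lists were therefore not run, and regions are given by position without a gene name. Peaks on sequences other than chromosomes 1 to 22 and X were left out of all results but one alternative. The code for overlaps, regions and classes was tested on simulated lists with 3870 strong peaks per library, and all 6 planted quantities were recovered exactly. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and the figures used matplotlib 3.10.9.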

Results

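To compare where YAP and TAZ occupy chromatin in H1299 lung cancer cells, 4 lists of broad peaks were analysed, 2 from YAP and 2 from TAZ immunoprecipitations of serum-starved cells. The lists were long. On chromosomes 1 to 22 and X, the YAP libraries held 392120 and 353336 peaks and the TAZ libraries 333505 and 310657. Deposited peaks covered 514 and 449 Mb in the YAP libraries and 405 and 425 Mb in the TAZ libraries. The mean number of peaks was 372728 ± 27424 for YAP and 322081 ± 16156 for TAZ (SD, n = 2), a ratio of 1.16. Both YAP lists were longer than both TAZ lists, but the exact two-sided permutation test gave p = 0.333, the smallest value that 2 libraries against 2 allow. The difference of 50647 peaks became 31255 without YAP replicate 1 and 89241 among peaks with a q-value of at most 0.01. Among peaks with a fold of at least 4 it was 6533.5, and the antibodies overlapped, with 36163 and 26580 peaks for YAP and 32268 and 17408 for TAZ (exact two-sided permutation p = 0.667). The read depth behind the lists is unknown, so list length cannot be separated from depth.

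Most deposited peaks were narrow and weakly enriched. The median width was 613 and 629 bp in the YAP libraries and 638 and 717 bp in the TAZ libraries. The authors' median fold over input was 3.14 in both YAP libraries, 3.16 in TAZ replicate 1 and 3.03 in TAZ replicate 2. A fold of at least 4 was reached by 9.22% and 7.52% of the YAP peaks and by 9.68% and 5.60% of the TAZ peaks. The largest fold was 9.03 and 10.4 in the YAP libraries and 9.57 and 8.07 in the TAZ libraries. Some peaks were very wide. The widest peak of YAP replicate 1 spanned 88167 bp on chromosome 21 from 10772662 to 10860828, and the widest peaks of YAP replicate 2 and TAZ replicate 1 lay at nearly the same place. The widest peak of TAZ replicate 2 spanned 135931 bp on chromosome 9 from 139829834 to 139965764.

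Peaks of both antibodies were unevenly spread over the chromosomes. Deposited peaks covered 49.5% ± 1.2 of chromosome 19 in the YAP libraries and 48.6% ± 2.9 in the TAZ libraries (SD, n = 2). Chromosome 17 followed with 32.1% ± 1.6 for YAP and 30.8% ± 2.5 for TAZ. The lowest coverage was on chromosome X, with 6.53% ± 1.77 for YAP and 4.45% ± 0.45 for TAZ, and on chromosome 13, with 7.94% ± 1.58 for YAP and 5.98% ± 0.14 for TAZ. Strong peaks, the 20000 best-ranked peaks of each library, followed another order. Chromosome 6 had 17.0 ± 1.6 strong peaks per Mb for YAP and 15.3 ± 0.48 for TAZ, and chromosome 19 had 16.7 ± 1.6 and 13.1 ± 0.81. Chromosome X had 0.325 ± 0.150 for YAP and 0.673 ± 0.032 for TAZ. The difference of chromosome X from chromosomes 6 and 19 was far larger than the spread between libraries of 1 antibody; that between chromosomes 6 and 19 for YAP was not.

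**Figure D1:**
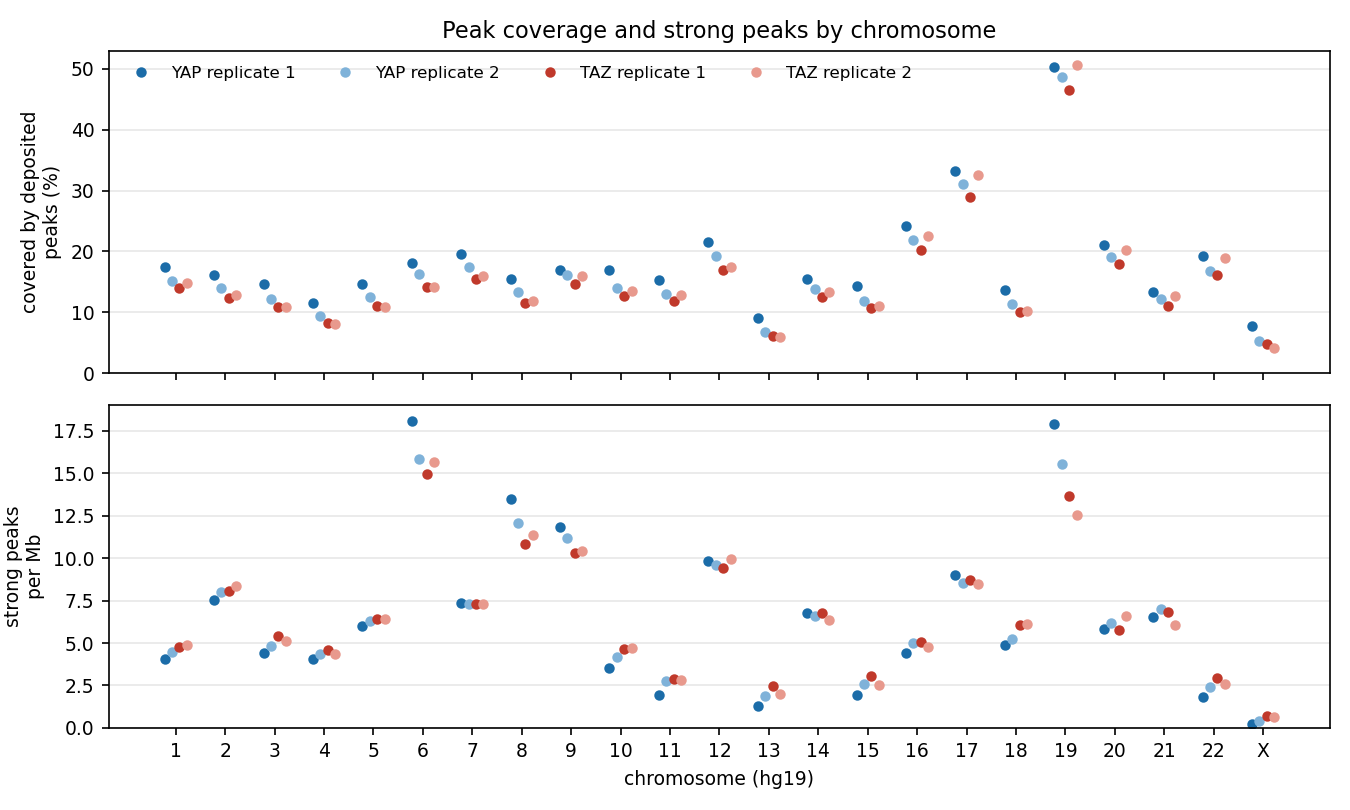
Share of each chromosome covered by deposited peaks (upper panel, percent) and strong peaks per Mb (lower panel), with 1 point per library and chromosome; blue points are YAP and red points TAZ libraries. Coverage was highest on chromosome 19, where the means were 49.5% for YAP and 48.6% for TAZ, and strong peaks were densest on chromosomes 6 and 19 in all 4 libraries.

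Within the chromosomes, strong peaks crowded into the same stretches with both antibodies. Across 574 windows of 5 Mb, the number of strong peaks in any pair of libraries had a Spearman's rho between 0.954 and 0.961, whether or not the pair shared an antibody. These windows are not independent replicates. The fullest window with both antibodies was chromosome 19 from 35000001 to 40000000, with 277.5 ± 38.9 strong peaks for YAP and 191.5 ± 0.71 for TAZ (SD, n = 2). The windows on either side of it, from 30000001 to 35000000 and from 40000001 to 45000000, held 241 ± 26.9 and 234 ± 42.4 for YAP. For TAZ they held 174.5 ± 7.8 and 172.5 ± 19.1. On chromosome 12, the window from 40000001 to 45000000 held 220.5 ± 14.8 strong peaks for YAP and 172 ± 9.9 for TAZ. The −log10 p of peaks of similar fold was also highest in such windows: in YAP replicate 1 its median was 6.61 in the tenth of windows with the most strong peaks and 4.96 in the tenth with the fewest. Strong peaks were chosen by −log10 q, which rises with −log10 p, so part of this difference is built in.

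The question the series poses, how far YAP and TAZ bind the same places, was first addressed by the overlap of strong peaks between libraries. The YAP libraries overlapped with a Jaccard index of 0.177, and the TAZ libraries with 0.126. Between antibodies, the index was 0.150 for the libraries numbered 1 and 0.128 for those numbered 2. For libraries of different numbers it was 0.133 (YAP replicate 1 with TAZ replicate 2) and 0.127 (YAP replicate 2 with TAZ replicate 1). At this list length, each of the 4 pairs of a YAP with a TAZ library had a higher index than the TAZ pair. With 5000 strong peaks per library all 4, at 0.141 to 0.166, lay below the TAZ pair, at 0.168, and with peaks ranked by fold YAP replicate 2 with TAZ replicate 1, at 0.0446, lay below the TAZ pair, at 0.0526. In shares of peaks, 21.5% of the strong peaks of YAP replicate 1 overlapped one of YAP replicate 2 (95% Wilson interval 20.9 to 22.1%), and 20.7% overlapped one of TAZ replicate 1 (20.1 to 21.3%).

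Every pair overlapped more than shifted lists did. Shifts anywhere along the chromosomes gave a mean Jaccard index between 0.00542 and 0.00872, and the observed indices were 17.5 to 23.2 times these means. Shifts by 20 to 100 kb, which keep the crowding of peaks, gave means between 0.0229 and 0.0416, and the observed indices were 3.92 to 5.48 times as high. The TAZ pair had the highest ratio to chance of the 6 pairs with both kinds of shift. The mean index within antibodies, 0.151, exceeded the mean between antibodies, 0.135, by 0.0169. This was the highest of the 3 ways to pair the 4 libraries; pairing by replicate number gave -0.00150 and crossed pairing -0.0154. With only 3 ways, no share under 0.05 is possible. The contrast depended on the ranking and on single libraries: it was -0.00128 when peaks were ranked by fold (0.00743 when set only against between-antibody pairs of different numbers), -0.00201 without YAP replicate 1, -0.0158 without YAP replicate 2, 0.0470 without TAZ replicate 1 and 0.0383 without TAZ replicate 2.

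**Figure D2:**
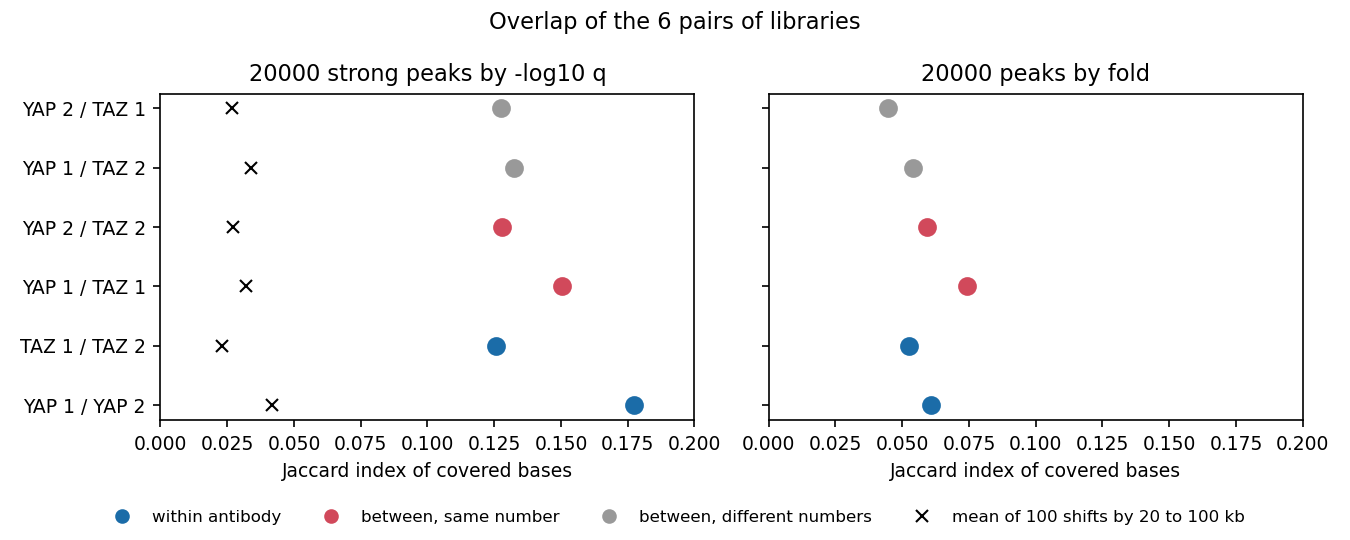
Jaccard index of covered bases (horizontal axis) for the 6 pairs of libraries (vertical axis), for the 20000 peaks with the highest −log10 q (left) and the 20000 with the highest fold (right). Circles are observed values coloured by kind of pair. Crosses, on the left only, are means of 100 shifts by 20 to 100 kb, which were not run for the fold ranking. With the −log10 q ranking the YAP libraries overlapped most (0.177), and with the fold ranking YAP replicate 1 and TAZ replicate 1 did (0.0741).

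Over regions with strong peaks in both libraries of a pair, the authors' fold had a positive rank correlation in every pair, the size of which depended on how strong peaks were chosen. Spearman's rho across regions was 0.508 between the YAP libraries (4268 regions) and 0.477 between the TAZ libraries (3572 regions). It was 0.572 between YAP and TAZ replicate 1 and 0.575 between YAP and TAZ replicate 2, and 0.423 and 0.499 for YAP and TAZ libraries of different numbers. With strong peaks chosen by fold instead, rho was between 0.0587 and 0.124 in the 6 pairs. That choice narrows the range of the fold that is then correlated, so a lower rho is partly built in. The mean rho within antibodies minus the mean between them was -0.0246. Libraries of 1 antibody always differ in number, and against the between-antibody pairs of different numbers alone the difference was 0.0316. Against all between-antibody pairs, the difference changed sign to 0.0114 with peaks ranked by fold and to 0.00965 without TAZ replicate 1. Regions are not independent replicates, and no p was computed.

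Strong peaks of the 4 libraries merged into 61788 regions. Of these, 4264 were reproducible for YAP, 3577 were reproducible for TAZ and 788 were shared, that is, strong in all 4 libraries. When both TAZ lists were shifted anywhere along the chromosomes, 42.1 ± 20.04 regions were shared (SD of 100 shifts, highest 97). With shifts by 20 to 100 kb the number was 146 ± 8.9 (highest 166), so the observed number was 5.41 times the local chance level. The size of the shared class followed the length and ranking of the lists: 186 regions with 5000 strong peaks per library, 4079 with 50000, and 245 with 20000 peaks ranked by fold.

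Shared regions were wider than most and were unevenly spread over the chromosomes. Their median width was 1455 bp, against 693.5 bp for reproducible YAP, 739 bp for reproducible TAZ and 460 bp for all regions. Part of this follows from the definition, since a shared region merges strong peaks of all 4 libraries and a wider region meets more of them. Chromosome 19 held 130 of them (16.5%), chromosome 6 held 98, chromosome 9 held 76 and chromosome 12 held 67. Chromosome 13 held 0, chromosome 22 held 1 and chromosome X held 5. These counts were not set against the number of strong peaks on each chromosome, so they do not by themselves show an excess or a lack. Strong peaks too were sparse on chromosome 13, with 1.59 per Mb for YAP and 2.25 for TAZ, and on chromosome 22, with 2.13 and 2.75. Near a long peak-free stretch lay 108 shared regions, or 13.7% (95% Wilson interval 11.5 to 16.3%). The share was 5.32% of reproducible YAP regions, 4.61% of reproducible TAZ regions and 1.31% of all regions. Among the 50 shared regions with the lowest rank sum, 23 lay near such a stretch (46%, 95% Wilson interval 33 to 59.6%). Without peaks near such stretches, 680 regions were shared. The median fold in shared regions was not above that of all strong peaks. In each library it was taken from the region's peak with the highest −log10 q. Its median was 4.14 and 4.03 in the YAP libraries and 4.18 and 3.91 in the TAZ libraries. For all strong peaks of the same libraries, the shared ones included, the medians were 4.43, 4.35, 4.50 and 4.21.

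The shared region with the lowest rank sum lay on chromosome 21 from 9825290 to 9827669, with a fold of 2.60 and 3.40 in the YAP libraries and 3.77 and 5.75 in the TAZ libraries. The next lay on chromosome 6 from 58776096 to 58779455, at the edge of a peak-free stretch, with a fold of 1.59 and 2.26 for YAP and 2.37 and 2.61 for TAZ. A region on chromosome 17 from 25262990 to 25268118, also beside such a stretch, had a fold of 3.66 and 3.79 for YAP and 3.69 and 3.51 for TAZ. The region on chromosome 1 from 156183719 to 156187434 had 2.20 and 2.85 for YAP and 3.61 and 3.99 for TAZ. The region on chromosome 11 from 85194820 to 85195451 had no other strong peak within 15 kb and had almost the same borders in all 4 libraries, with a fold of 2.49 and 2.84 for YAP and 4.01 and 4.22 for TAZ. These 5 regions ranked high by −log10 q at a fold that was mostly below the median of strong peaks. In YAP replicate 1 the peak of the chromosome 11 region had a fold of 2.49 and a −log10 q of 29.9. A narrower peak nearby, from 85183396 to 85183657, had a fold of 2.50 and a −log10 q of 1.98. No list of artefact-prone regions was applied, so a technical origin of these or other named regions was not tested.

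**Figure D3:**
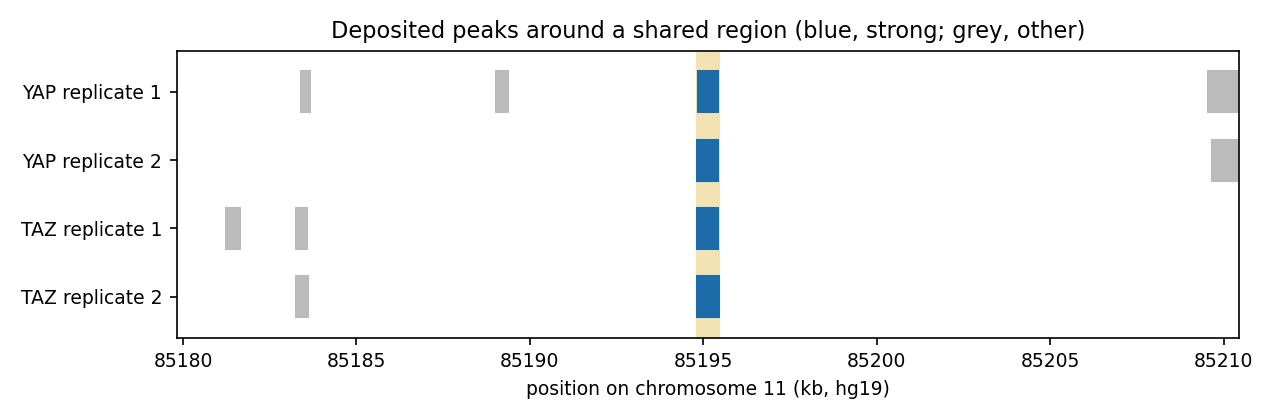
Deposited peaks of the 4 libraries within 15 kb of the shared region on chromosome 11 from 85194820 to 85195451 (horizontal axis, position in kb on hg19; 1 line per library). Blue boxes are strong peaks, grey boxes are other deposited peaks and the shaded band is the shared region; the only strong peaks in this stretch were the 4 in the band.

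Regions bound by 1 antibody without any peak of the other were rare. Of the 4264 reproducible YAP regions, 98.4% overlapped a deposited peak of at least 1 TAZ library (95% Wilson interval 97.9 to 98.7%) and 87.3% overlapped peaks of both (86.3 to 88.3%). Of the 3577 reproducible TAZ regions, 99.7% overlapped a deposited peak of at least 1 YAP library (99.5 to 99.8%) and 96.0% overlapped peaks of both (95.3 to 96.6%). This left 70 YAP-selective and 11 TAZ-selective regions. Shifting the TAZ lists by 20 to 100 kb gave 2306 ± 28.4 and 1904 ± 25.5. Asking only for strong peaks, 52.0% of the reproducible YAP regions overlapped one of at least 1 TAZ library and 18.5% overlapped those of both; for reproducible TAZ regions the shares were 55.6% and 22%.

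Selective regions were also found when the libraries were paired otherwise. Regions strong in both libraries numbered 1 with no peak in either numbered 2 came to 54, and the reverse to 12. The crossed pairing gave 12 and 12. YAP replicate 1, the longest list, was among the first-named libraries of each pairing. The excess of YAP-selective over TAZ-selective regions also followed list length: with all deposited peaks the counts were 31105 and 6511, and with every list shortened to the length of the shortest they were 19940 and 13186. With a reciprocal overlap of 50% they were 284 and 260, but these count strong peaks of replicate 1 of each antibody, not merged regions. Leaving out 1 library drops the need for 2 replicates for its antibody alone, which by construction favours that antibody. It also leaves only 1 list of that antibody that must lack a peak, which by construction raises the other antibody's count too. The counts were 347 and 345 without TAZ replicate 1 and 266 and 285 without TAZ replicate 2. They were 1265 and 116 without YAP replicate 1 and 1008 and 37 without YAP replicate 2.

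**Figure D4:**
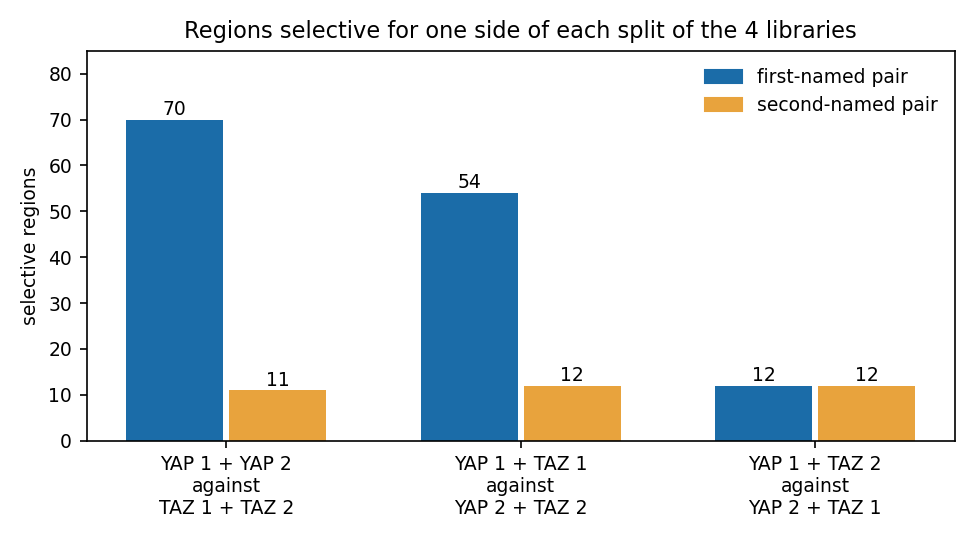
Number of selective regions (vertical axis) for the 3 ways to divide the 4 libraries into pairs (horizontal axis); blue bars are regions strong in both libraries of the first-named pair with no deposited peak in the other pair, orange bars the reverse. Division by antibody gave 70 and 11, by replicate number 54 and 12, and crossed 12 and 12.

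YAP-selective regions had a median width of 439.5 bp, against 460 bp for all regions. Of the 70, 16 lay on chromosome 6, where strong peaks were also dense for YAP (17.0 per Mb). The region with the lowest rank sum lay on chromosome 6 from 1883276 to 1883708, with a fold of 5.02 and 4.66. The next, on chromosome 1 from 142586857 to 142587205, had 3.85 and 3.47 and lay near a peak-free stretch. On chromosome 8, the region from 127730842 to 127731278 had a fold of 4.49 and 4.73, and that from 105507822 to 105508279 had 4.42 and 4.27. The fifth, on chromosome 5 from 140341397 to 140341799, had 4.73 and 4.91.

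The 11 TAZ-selective regions had a median width of 378 bp. The region with the lowest rank sum lay on chromosome 8 from 90322358 to 90322775 and had a fold of 6.52 and 5.34, the highest among the named selective regions. The region on chromosome 4 from 49512334 to 49512648, near a peak-free stretch, had a fold of 1.98 and 2.09, and that on chromosome 2 from 133018591 to 133018912 had 2.09 and 2.23. The region on chromosome 1 from 48639908 to 48640430 had 5.36 and 4.50. The last of the 5, on chromosome 21 from 14416263 to 14416640, near a peak-free stretch, had 3.94 and 5.21. Near a peak-free stretch lay 3 of the 11 TAZ-selective regions (27.3%, 95% Wilson interval 9.75 to 56.6%) and 3 of the 70 YAP-selective regions (4.29%, 1.47 to 11.9%).

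Few strong peaks lacked any overlap with the deposited peaks, of any rank, of the other libraries. Those lists are long, and no shifted lists were used here, so the shares below have no chance level. Among strong peaks alone, 21.5% of those of YAP replicate 1 overlapped one of YAP replicate 2. For TAZ, 18.0% of those of replicate 1 overlapped one of replicate 2. In YAP replicate 1, 314 of the 20000 strong peaks (1.57%) overlapped no deposited peak of any other library; the numbers were 220 (1.10%) in YAP replicate 2, 166 (0.830%) in TAZ replicate 1 and 176 (0.880%) in TAZ replicate 2. The best-ranked of these in YAP replicate 1 lay on chromosome 6 from 19105663 to 19106485, with a fold of 2.03. In TAZ replicate 1 it lay on chromosome 9 from 70952367 to 70952688, with a fold of 6.5.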

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

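The alternatives for rank agreement, the restriction to pairs of different numbers, the lists shortened to the shortest, the removal of peaks near peak-free stretches and the omission of libraries for peak number were chosen after seeing the data. The YAP minus TAZ difference in peak number kept its sign in all 8 alternatives, but most of them could not have reversed it. Both YAP lists were longer than both TAZ lists, so leaving out 1 library had to keep the sign (31255 to 70039). The replicate block returns the same difference, and all sequences in the lists added few peaks. The difference was 89241 at a q-value of at most 0.01 and 6533.5 at a fold of at least 4. No alternative could pass a threshold. The within minus between contrast of the Jaccard index kept its sign in 11 of 14 alternatives. It reversed to -0.00128 with peaks ranked by fold, to -0.00201 without YAP replicate 1 and to -0.0158 without YAP replicate 2 (range -0.0158 to 0.0470 with 1 library left out). The cause was not tested; without a YAP library only the TAZ pair is left within antibodies. The contrast of rank agreement reversed to 0.0114 with peaks ranked by fold and to 0.00965 without TAZ replicate 1 (range -0.0603 to 0.00965), and the cause was not tested. Set only against between-antibody pairs of different numbers it reversed to 0.0316, or 0.0307 with peaks ranked by fold, so its negative sign rests on the same-number pairs. The Jaccard contrast was then 0.0215, or 0.00743 with peaks ranked by fold.

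Counts of regions moved with the number of peaks admitted, by construction. Shared, YAP-selective and TAZ-selective regions numbered 186, 8 and 3 with 5000 strong peaks per library, 4079, 408 and 52 with 50000, 177445, 31105 and 6511 with all deposited peaks, and 148807, 19940 and 13186 with every list shortened to the shortest. Ranking by fold gave 245 shared regions. A reciprocal overlap of 50% gave 284 for YAP and 260 for TAZ. These count selective strong peaks of replicate 1 of each antibody, not merged regions. Such a peak may still overlap a peak of the other antibody, for example by lying inside a much wider one. Leaving out 1 library, which removes the need for 2 replicates, gave 1295 to 1504 shared, 266 to 1265 YAP-selective and 37 to 345 TAZ-selective regions. YAP-selective regions outnumbered TAZ-selective ones in every setting with all 4 libraries. Without 1 library the antibody left with 1 replicate gains by construction. The other antibody gains as well, since only 1 opposing list must then lack a peak. The counts were 347 against 345 without TAZ replicate 1 and 266 against 285 without TAZ replicate 2. They were 1265 against 116 without YAP replicate 1 and 1008 against 37 without YAP replicate 2.

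The replicate numbers were not taken to pair the libraries. The labels tie none together; the names of the lists point to 1 input per number but the peak names inside them to a common one, so a shared input stays open. The replicate 1 minus 2 deviations of YAP and TAZ had a correlation of 0.112 across 25277 windows of 100 kb. With the replicate number as a block, the difference in peaks was 50647, the Jaccard contrast 0.0123 and the contrast of rank agreement -0.0807; these contrasts set pairs of different numbers within antibodies against same-number pairs between them, so they do not remove an effect of the number. Sign flips of 2 pairs cannot give a p below 0.5. Unknown read depth limits every comparison of list length. Genomic features, motifs, promoter genes and gene lists were planned and not run, with all their alternatives.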

Other observations

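The tests of replicate number and of the antibody as the source of the chromosome trend, and the rule for shorter peak-free stretches, were chosen only after the results were seen. Chromosomes rich in genes were covered more by peaks of both antibodies. Across the 23 chromosomes, the share covered by deposited peaks rose with the number of protein-coding genes per Mb in every library. For YAP, Pearson's r was 0.947 and 0.943 and Spearman's rho 0.781 and 0.767; for TAZ, r was 0.951 and 0.952 and rho 0.792 and 0.810. The permutation p of r was 1e-05 in each library, the smallest the resamples can give (adjusted 3.5e-05), and the adjusted p of rho lay between 4.7e-05 and 0.00017. Without chromosomes 17 and 19, which lie farthest from the median gene density, r was 0.699 and 0.675 for YAP and 0.713 and 0.740 for TAZ. Peaks per Mb followed gene density less closely, with a rho of 0.312 and 0.399 for YAP (adjusted permutation p = 0.15 and 0.07) and 0.522 and 0.602 for TAZ (0.016 and 0.0047). Gene counts came from another build, and chromosomes of 1 cell line are not independent samples of cells.

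Peaks of all 4 libraries were missing together from 38 stretches of 200 kb to 1 Mb. Of these, 35 lay over 1 Mb from the long stretches, and in 24 the density of the 1 Mb on both sides would have given at least 10 peaks in every library. The longest lay on chromosome 15 from 82579533 to 83214873 (635 kb), where the flanking density corresponded to 68.0 to 92.8 peaks. On chromosome 10, from 17831931 to 18206724 (375 kb), it corresponded to 41.2 to 61.7, and on chromosome 4, from 19486254 to 19815860 (330 kb), to 25.4 to 39.2. On chromosome 13, the stretches from 93986039 to 94235533 and from 94235812 to 94545237 were neighbours. These examples were singled out after their values were seen. Gaps in the reference sequence and repeats were not analysed here.

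Strong peaks crowded into blocks such as chromosome 19 from 30 to 45 Mb. If local read depth, for example the copy number of a segment, set these blocks, peaks of similar fold should have larger −log10 p there. The median −log10 p was taken over peaks with a fold of 3 to 3.5 and at most 500 bp. Its rho with the number of strong peaks was at least 0.875 in each library (permutation p = 1e-05, the smallest possible). Strong peaks were themselves chosen by −log10 q, which rises with −log10 p, so part of this rho is built in. The permutation also treats windows as independent, which neighbouring ones are not. Between the strong peaks of a library and the median −log10 p of the other libraries, the mean rho was 0.895 to 0.905. The tie within a library is therefore not the whole of it. However, the libraries crowd into the same windows and may share an input, so depth as an account of the blocks stays open. Crowding of binding sites also stays open: strong peaks ranked by fold filled the same windows, with a rho of 0.862 to 0.905 in the 4 libraries. Because the fold itself can vary with depth, these tests do not separate the explanations, and no copy number was measured here.

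With lists ranked by fold, libraries of the same number overlapped more on average than others, with a contrast of 0.0137 against -0.00128 by antibody and -0.0124 crossed. The pair numbered 1 had the highest Jaccard index, 0.0741, whereas the pair numbered 2, at 0.0593, lay below the YAP pair, at 0.0609. In the −log10 q ranking the split by number came after the split by antibody (-0.00150 against 0.0169). The rank agreement of the fold in that ranking was nevertheless highest in the same-number pairs. Their rho was 0.572 and 0.575, against 0.508 in the YAP pair, the next highest. With peaks ranked by fold, the pair numbered 2, at 0.0930, lay below the TAZ pair, at 0.121. Conditions shared by a replicate number, such as a common input or preparation, may contribute, and the design cannot tell: there are only 3 splits, and which input was used is unsettled. Selective binding of 1 antibody stays untested for the same reason.

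The ratio of YAP to TAZ peaks, highest on chromosome X (1.31) and lowest on chromosome 22 (1.01), fell with gene density across chromosomes (rho -0.818, r -0.687, adjusted permutation p of rho 4.7e-05; r -0.715 without chromosomes 17 and 19). The length of the lists as the whole cause is argued against by the lists shortened to 1 length, where rho was -0.716 (adjusted permutation p = 0.00023) and r a weaker -0.487 (0.035). The high ratio on chromosome X was not kept in the shortened lists. It held 43.9 and 44.1 peaks per Mb there for YAP, fewer than the 49.0 and 46.9 for TAZ. Whether the antibody contributes stays open: the rho of -0.818 was the most negative of the 3 splits, with -0.661 by replicate number and -0.450 crossed, while r of the crossed split was -0.701, or -0.258 without chromosomes 17 and 19. Within antibodies, rho was -0.603 for the ratio of the YAP libraries (r -0.590) and -0.340 for that of the TAZ libraries (r 0.049), and without chromosomes 17 and 19 r was -0.422 and -0.479. Differences between single libraries, such as depth, therefore stay open as well.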
